A study of Oryza sativa with 8 samples.

How the data were processed

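Flag leaf RNA of 8 rice libraries was compared, 2 of the wild type, 3 labelled GSK2-RNAi and 3 labelled GSK2-RNAi oswrky53. Groups and replicate numbers were taken from the sample labels, and each table column was matched to a sample by its title. Libraries were made from total RNA with an Illumina TruSeq RNA kit, per the sample labels.

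The authors deposited 1 table of normalized counts, a signal per transcript that is never negative, for 38335 transcripts of 32166 genes. The submitters' processing notes name kallisto 0.46.1, DESeq2 1.26.0 and build IRGSP-1.0, with no order or role; the annotation and the normalization are not given in the sources used here. Low values in each library lay near multiples of 1 step, taken as the approximate value of 1 read, but spread around it by transcript: between 63.3% and 98.7% of values up to about 20 steps lay within 0.1 step of a multiple. Whole reads were therefore not recovered, and no count model was run. Intervals from approximate reads would cover counting error only, and none are given.

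Transcript values were summed per gene. Genes with at least 10 in at least 2 libraries were kept, which left 25325. The values were used as deposited, without further scaling, as log2(value + 1), so a log2 fold change understates the change of low genes. Each comparison was a contrast of 3 group means fitted to all 8 libraries with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with an intensity trend), and genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. The wild type group of 2 libraries shares the estimate of spread with the others. Fold values in the text are ratios of group means of normalized counts, and values with an error are the mean ± SD of a group or the log2 fold change ± SE of the fit. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

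The deposited table holds identifiers without names, and the reference table used here (assembly ASM3414082v1) holds names without these identifiers. Names were therefore paired with identifiers by hand, from general knowledge of rice genes, and 430 such pairs were written. To pass, the symbol had to stand in the reference table on the chromosome of the identifier and in the matching order along it, within 1 Mb. This held for 294 pairs. Those whose identifier is in the deposited table were used, which with WRKY53 made 278 pairs. Of these, 46 were written before the table of values arrived and 232 after it had arrived but before any comparison was run. Of 306 symbols found in the reference table, 7 stood on another chromosome and 5 out of order, and these were dropped. WRKY53 is the exception: it is named in the genotype label, its symbol is not in the reference table, and its pair was not checked. The order check cannot tell apart neighbouring members of a gene family. No coordinates are given, because the builds differ.

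Most of the 25 gene lists were planned by name before the data were examined. The list of leaf angle and grain size was added afterwards, members of most lists were written afterwards though before any comparison, and several planned lists were joined where few members passed the name check. With only the members written before, of the called lists that of clock and flowering time alone kept the 5 members needed for a set test (15 of its 17), with camera adjusted p = 0.00213 in the libraries labelled GSK2-RNAi against the wild type and 0.00076 in those labelled GSK2-RNAi oswrky53 against those labelled GSK2-RNAi. Here the adjustment ran only over lists that kept 5 such members, so these values cannot be set against those of the full lists. MADS50 is among the members left out. The list of plastid-encoded genes had no member among the identifiers, and families planned by product description could not be formed. Lists were tested with limma's camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 22 lists with at least 5 measured members. With an estimated correlation no list was called in any comparison. With limma's fry, which tests the members without regard to other genes, 13 list calls were made over the comparisons. Named genes followed a rule fixed before the data were examined: GSK2 and WRKY53; for the comparisons of the libraries labelled GSK2-RNAi with the wild type and of the libraries labelled GSK2-RNAi oswrky53 with those labelled GSK2-RNAi, the 8 largest rises and 8 largest falls among called genes with a checked name, groups that do not overlap and a mean of at least 50; for the remaining comparison 4 and 4, of which none had a name, the plan's product descriptions being unavailable for these identifiers; up to 4 called members of each list; and 8 genes for the return toward the wild type.

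The fit was tested on simulated libraries built from the real gene means with 200 changed genes, 100 by 2-fold and 100 by 4-fold. For the libraries labelled GSK2-RNAi against the wild type it recovered 23.0% of the 2-fold and 67.0% of the 4-fold changes among 24798 genes tested, with 7 false calls. For the libraries labelled GSK2-RNAi oswrky53 against those labelled GSK2-RNAi it recovered 43.0% and 65.0% among 24807 genes, with 7 false calls. For the libraries labelled GSK2-RNAi oswrky53 against the wild type it recovered 29.0% and 64.0% among 24810 genes, with 8 false calls. The first and second of these comparisons called 6290 and 4172 genes in the real data, against 200 changed genes here. The Benjamini-Hochberg cut-off is stricter where few genes change, so these shares need not hold for those comparisons.

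Alternatives were other pseudocounts (0.5 and 8), filters, scalings (trimmed mean of M values, upper quartile, quantile), eBayes without trend or robust, library weights, fits of only the compared groups, the replicate number as a block, a 2-fold minimum, transcripts in place of genes, other set tests and leaving out each library. Scaling to equal library totals and lists of only the members written before the table arrived were added after the data were seen. Count tests planned for the case of recovered reads were not run.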

Results

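Messenger RNA of rice flag leaves (cultivar ZH11) was measured in 8 libraries of 3 genotypes. The wild type had 2 libraries, numbered 1 and 3 in the labels. The genotype labelled GSK2-RNAi, in which an RNA interference construct is directed at GSK2, had 3 libraries, as did the genotype labelled GSK2-RNAi oswrky53, which joins that construct with a mutation of WRKY53. GSK2 is a kinase that restrains brassinosteroid signalling, and WRKY53 is a transcription factor. The sample labels place the harvest at heading, and the series text places it at booting. In units of 1e6, the summed normalized counts were 28.03 and 27.74 in the wild type libraries, 21.49, 20.87 and 21.71 in the libraries labelled GSK2-RNAi, and 26.67, 27.04 and 25.98 in the libraries labelled GSK2-RNAi oswrky53. Dividing each total by the approximate value of 1 read gave depths from 19.87 to 38.69 in units of 1e6 reads. The 100 most abundant genes held between 21.3% and 22.6% of the total in the libraries labelled GSK2-RNAi and between 28.5% and 31.7% in the other 5 libraries. The labels do not say whether the libraries of a genotype came from separate plants, so the p-values measure the spread between these samples only.

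The transcript named by the RNA interference label went against that label. GSK2 (Os05g0207500, chromosome 5) was at 102 ± 4.25 normalized counts in the wild type (SD, n = 2), at 785 ± 39.99 in the libraries labelled GSK2-RNAi (SD, n = 3) and at 185 ± 32.2 in the libraries labelled GSK2-RNAi oswrky53 (SD, n = 3). The log2 fold change of the libraries labelled GSK2-RNAi against the wild type was 2.94 ± 0.17 (SE, limma adjusted p = 0.000107), a 7.73-fold higher mean, and every one of these 3 libraries lay above the other 5. Against the libraries labelled GSK2-RNAi, those labelled GSK2-RNAi oswrky53 fell by 2.09 ± 0.15 on the log2 scale (SE, limma adjusted p = 0.00067). Against the wild type they differed by 0.85, which did not pass the threshold (limma adjusted p = 0.102). Because the level goes against the label, the groups are named by their labels throughout, and no direction below stands for the effect of a lower GSK2 transcript. WRKY53 (Os05g0343400, chromosome 5) was at 3600 ± 554 normalized counts in the wild type, 7933 ± 587 in the libraries labelled GSK2-RNAi and 8423 ± 2892 in those labelled GSK2-RNAi oswrky53. It rose in the libraries labelled GSK2-RNAi by 1.15 ± 0.26 on the log2 scale against the wild type (SE, limma adjusted p = 0.0152), a call that was lost without wild type replicate 3 (0.99, adjusted p = 0.0819). The libraries labelled GSK2-RNAi oswrky53 differed from those labelled GSK2-RNAi by 0.03 (limma adjusted p = 0.939), a difference whose sign changed with the scaling, and from the wild type by 1.18 (limma adjusted p = 0.133). The labels do not say how WRKY53 was mutated, so its transcript level does not test the genotype, and the pairing of this name with its identifier was not checked against a reference table.

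**Figure D1:**
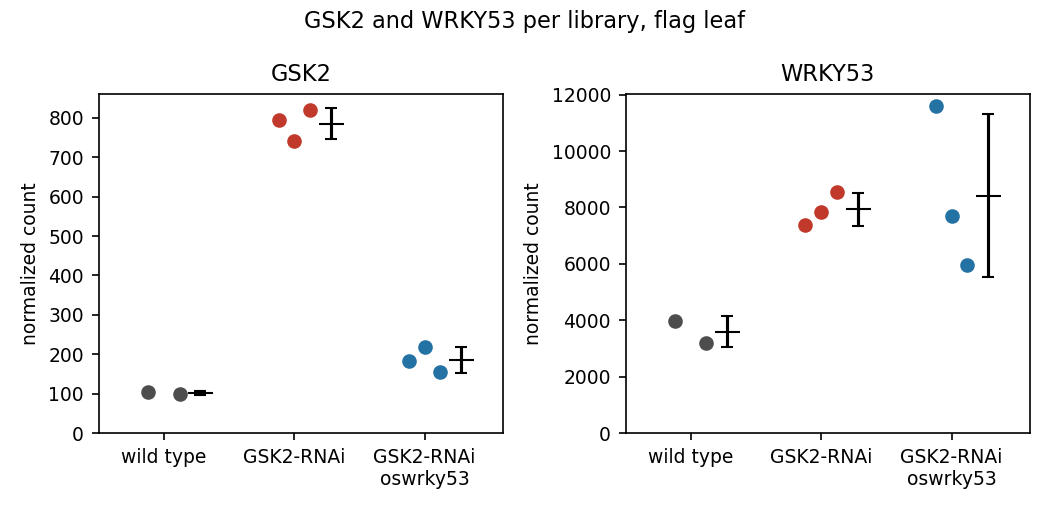
Normalized counts of GSK2 (left) and WRKY53 (right) in each of the 8 libraries, by labelled genotype; points are libraries and the black bars are the mean ± SD. GSK2 lies near 100 in both wild type libraries, between 741 and 820 in the libraries labelled GSK2-RNAi and between 155 and 219 in those labelled GSK2-RNAi oswrky53.

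The comparison of the libraries labelled GSK2-RNAi with the wild type asked which flag leaf transcripts go with that construct. In the libraries labelled GSK2-RNAi 4 of 6 brassinosteroid synthesis genes, 7 of 11 cytokinin genes and 7 of 14 genes of photosynthesis and chlorophyll synthesis fell, while 4 of 4 phenylpropanoid and lignin genes, 2 of 4 chlorophyll breakdown genes and 6 of 12 jasmonate genes rose. DWF4 (Os03g0227700), a brassinosteroid synthesis hydroxylase, went from 682 ± 525 to 55.7 ± 15.7 normalized counts (SD, n = 2 and 3), and the cytokinin response regulator RR4 (Os01g0952500) from 2763 ± 177 to 534 ± 53.1. RCCR1 (Os10g0389200), a reductase of chlorophyll breakdown, went from 108 ± 44.3 to 1770 ± 951, and 4CL3 (Os02g0177600), a ligase of the lignin pathway, from 322 ± 15.3 to 1889 ± 378. In all, 6290 of 25325 genes tested changed, 3364 upward and 2926 downward.

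Of the 6 brassinosteroid synthesis genes measured, 4 fell and 0 rose in the libraries labelled GSK2-RNAi, and of 3 genes of the CYP734A breakdown family 2 rose. DWF4 fell by 3.37 ± 0.50 on the log2 scale (SE, limma adjusted p = 0.00275), and D2 (Os01g0197100) fell by 1.96 ± 0.38 (adjusted p = 0.00837). CYP734A4 (Os06g0600400) was 19.4-fold higher, at 407 ± 233 against 20.98 ± 1.13. CYP90A4 (Os12g0139300) fell by 1.12, and it has a near-identical copy on another chromosome with which the authors' counting could share reads. The joint list of synthesis and breakdown genes, whose members went both ways, was not called as a set (camera adjusted p = 0.446). Among 16 brassinosteroid signalling genes 5 rose and 2 fell. The receptor gene BRI1 (Os01g0718300) was 2.48-fold lower and the kinase gene GSK4 (Os06g0547900) fell by 1.25, whereas the transcription factor gene BZR2 (Os01g0203000) rose by 0.72 on the log2 scale. GSK2 itself is among the 5 that rose, and the list was not called as a set (camera adjusted p = 0.995).

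In the cytokinin list 7 of 11 measured genes fell and 1 rose. The type-A response regulators RR4 and RR10 (Os12g0139400) fell by 2.37 ± 0.17 and by 2.28 ± 0.16 on the log2 scale (SE, limma adjusted p = 0.000257 and 0.000253), and RR2 (Os02g0557800) fell by 1.05. The gene that rose was CKX9 (Os05g0374200), which encodes a cytokinin-degrading oxidase, by 1.22. RR10 has a near-identical copy, RR9 (Os11g0143300), so their values may share reads. The list was called downward with a preset correlation (camera adjusted p = 0.0107), and the call was lost with an estimated correlation (adjusted p = 0.66 with an estimated correlation).

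In the list of photosynthesis and chlorophyll synthesis 7 of 14 genes fell and 0 rose. PSB28 (Os01g0938100), of photosystem II, fell by 2.03 ± 0.30 on the log2 scale (SE, limma adjusted p = 0.00275). The protochlorophyllide reductase gene PORB (Os10g0496900) fell by 1.41, from 27168 ± 8560 to 10021 ± 1163 normalized counts, and by 0.86 with quantile normalization. The magnesium chelatase subunit gene CHLI (Os03g0563300) fell by 1.41, a call that was lost without wild type replicate 3 (adjusted p = 0.0756). The list was called downward (camera adjusted p = 0.000325). The call was lost with an estimated correlation (adjusted p = 0.66 with an estimated correlation) and with quantile normalization (adjusted p = 0.165). The same libraries had the lower share of the 100 most abundant genes given above. Of 4 chlorophyll breakdown genes 2 rose and 0 fell. These were RCCR1, which was 16.3-fold higher (limma adjusted p = 0.000821), and the stay-green gene SGR (Os09g0532000), which went from 196 ± 187 to 2029 ± 1249 (adjusted p = 0.015; 0.0874 without wild type replicate 3 and 0.0519 without GSK2-RNAi replicate 2). With under 5 members that list had no set test. Of 8 genes of nitrogen uptake and assimilation 2 fell, among them the plastid glutamine synthetase gene GS2 (Os04g0659100), which fell by 1.40 (camera adjusted p = 0.494 for the list). With quantile normalization GS2 was lower by 0.68 and its call was lost (adjusted p = 0.0708).

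All 4 phenylpropanoid and lignin genes rose. PAL4 (Os02g0627100), of the entry step of the pathway, went from 4.41 ± 0.887 to 115 ± 15.8 normalized counts (limma adjusted p = 0.000829), COMT1 (Os08g0157500) was 4.92-fold higher and CAD2 (Os02g0187800) was 13.2-fold higher. In the list of defence proteins and signalling 4 of 15 genes rose and 1 fell (camera adjusted p = 0.342). The chitinase genes CHT1 (Os06g0726200) and CHT3 (Os06g0726100), which are neighbours, rose by 4.08 ± 0.60 and by 5.74 ± 0.92 on the log2 scale (SE, adjusted p = 0.0028 and 0.00375), and NPR1 (Os01g0194300), a salicylic acid coactivator, by 1.71. RAC1 (Os01g0229400), a small GTPase gene of immunity, fell by 2.84, a call lost without wild type replicate 3 (adjusted p = 0.105). Among 11 diterpenoid phytoalexin genes 2 rose and 2 fell. CPS4 (Os04g0178300) was 26.9-fold higher, whereas KSL5 (Os02g0571300) and KSL6 (Os02g0571800) fell by 1.94 and by 1.76 (camera adjusted p = 0.995 for the list). The KSL5 call was lost without wild type replicate 3 (adjusted p = 0.204) and without GSK2-RNAi replicate 1, 2 or 3 (0.0611, 0.107 and 0.0799), with equal totals (0.0539) and with eBayes without trend (0.0583), and the KSL6 call without wild type replicate 3 (0.144) and without GSK2-RNAi replicate 2 or 3 (0.0837 and 0.0774).

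In the jasmonate list 6 of 12 genes rose and 0 fell. The jasmonate repressor genes TIFY11D (Os10g0392400) and TIFY11B (Os03g0181100) rose by 2.92 ± 0.33 and by 2.20 ± 0.40 on the log2 scale (SE, limma adjusted p = 0.00117 and 0.00608), and TIFY10A (Os03g0402800) by 1.08. AOS2 (Os03g0225900), an allene oxide synthase gene of jasmonate synthesis, was at 1.4 and 0 in the wild type libraries and at 189, 498 and 318 in those labelled GSK2-RNAi. In the WRKY list 4 of 6 genes rose and 0 fell. WRKY24 (Os01g0826400) was 6.42-fold and WRKY51 (Os04g0287400) 1.93-fold higher, beside WRKY53 and WRKY71 (Os02g0181300), which was 3.37-fold higher with a call lost without wild type replicate 1 (adjusted p = 0.0525). Both lists were called upward (camera adjusted p = 0.00667 for jasmonate and 0.0107 for WRKY genes), and both calls were lost with an estimated correlation (adjusted p = 0.66 with an estimated correlation in each). The WRKY call was also lost with libraries scaled to equal totals (adjusted p = 0.0688) and without wild type replicate 3 (adjusted p = 0.115).

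In the list of clock and flowering time genes 3 of 17 fell and 1 rose. The flowering regulator MADS18 (Os07g0605200) was 2.31-fold lower, a call lost without wild type replicate 1 (adjusted p = 0.0604), and MADS50 (Os03g0122600) was 2.68-fold higher (limma adjusted p = 0.00129). The list was called downward (camera adjusted p = 0.0122), a call lost with an estimated correlation (adjusted p = 0.66 with an estimated correlation), with quantile normalization (adjusted p = 0.765) and without wild type replicate 1 (adjusted p = 0.0829). Among markers of other tissues and sample states, 0 of 5 genes of dividing cells and 0 of 6 floral organ and panicle genes passed (camera adjusted p = 0.995 for each). Of 4 pollen and anther genes 1 fell, TDR (Os02g0120500), by 1.48 (adjusted p = 0.0127; 0.0759 without wild type replicate 1). Of 11 heat shock genes 2 fell, among them HSFA2D (Os03g0161900) by 1.47 (camera adjusted p = 0.834). Of 12 genes of water stress and abscisic acid 2 rose and 4 fell (camera adjusted p = 0.995). Of these the abscisic acid synthesis gene NCED3 (Os03g0645900) was 3.84-fold higher, a call that was lost without wild type replicate 1 (adjusted p = 0.066). Adjusted over the list alone, the members that rose and fell numbered 2 and 8 for cytokinin, 0 and 8 for photosynthesis and chlorophyll synthesis, 6 and 0 for jasmonate, 4 and 0 for WRKY genes, 1 and 3 for clock and flowering time, 2 and 5 for brassinosteroid synthesis and breakdown, 6 and 6 for brassinosteroid signalling and 4 and 1 for defence.

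The counts come from limma with an intensity trend and a Benjamini-Hochberg adjusted p under 0.05. With libraries scaled to equal totals, an alternative chosen after the totals were seen, the median of all genes moved to 0.40 on the log2 scale and 8044 of 9507 changed genes were higher, against 3364 of 6290 with the deposited scaling. Small changes moved with it, that of BZR2 to 1.103, of CYP90A4 to -0.73 and of RR2 to -0.67. The count fell to 3727 without wild type replicate 1 and to 3670 without GSK2-RNAi replicate 2. Of 67 called genes chosen for naming, 28 lost the call without at least 1 of the libraries.

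The comparison of the libraries labelled GSK2-RNAi oswrky53 with those labelled GSK2-RNAi asked what the WRKY53 mutation changes in plants with the construct. The response regulator RR10 was 6.74-fold higher in the libraries labelled GSK2-RNAi oswrky53 (2325 ± 267 against 345 ± 35.5 normalized counts, SD, n = 3 each) and DWF4 was 7.25-fold higher, whereas RCCR1 was 12.3-fold lower (144 ± 6.50 against 1770 ± 951). The neighbouring transcription factor genes WRKY76 (Os09g0417600) and WRKY62 (Os09g0417800) were near 0 in all 3 libraries labelled GSK2-RNAi oswrky53. In all, 4172 of 25325 genes changed, 2223 upward and 1949 downward.

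In the cytokinin list 7 of 11 genes rose and 0 fell. RR10 rose by 2.75 ± 0.14 on the log2 scale (SE, limma adjusted p = 0.0003), RR9 by 2.31 ± 0.24, RR6 (Os04g0673300) by 2.24 ± 0.23 and RR4 by 1.90 ± 0.15. In the list of photosynthesis and chlorophyll synthesis 7 of 14 rose and 0 fell. PSB28 was 2.94-fold and PORB 2.41-fold higher (limma adjusted p = 0.00965 and 0.0103). PORB was higher by 0.78 on the log2 scale with quantile normalization. In the list of clock and flowering time 3 of 17 rose and 1 fell. Hd3a (Os06g0157700), a florigen gene, was at 252 ± 229 in the libraries labelled GSK2-RNAi and 1327 ± 607 in those labelled GSK2-RNAi oswrky53 (limma adjusted p = 0.0458), and MADS18 rose by 1.21. The Hd3a call was lost without GSK2-RNAi replicate 2 or 3 (adjusted p = 0.15 and 0.138) and without GSK2-RNAi oswrky53 replicate 2 or 3 (0.115 and 0.129), and with eBayes without trend (0.0815). These lists were called upward (camera adjusted p = 5.69e-05 for cytokinin, 5.69e-05 for photosynthesis and 0.0132 for clock and flowering time), and each call was lost with an estimated correlation (adjusted p = 0.502 with an estimated correlation in each). With quantile normalization the photosynthesis call (adjusted p = 0.0633) and the clock call (adjusted p = 0.593) were lost, the latter also without GSK2-RNAi replicate 3 (adjusted p = 0.0804). Adjusted over the list alone, the members that rose and fell numbered 7 and 0 for cytokinin, 9 and 0 for photosynthesis and 4 and 1 for clock and flowering time.

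Of the 6 brassinosteroid synthesis genes 4 rose and 0 fell, DWF4 by 2.82 ± 0.44 (SE, limma adjusted p = 0.00655) and D2 by 1.82 ± 0.34, and of the 3 breakdown genes 1 fell, CYP734A4, which was 6.25-fold lower with a call lost without GSK2-RNAi replicate 2 (adjusted p = 0.053). The list was not called as a set (camera adjusted p = 0.136). Of 16 brassinosteroid signalling genes 3 rose and 1 fell. BRI1 rose by 1.38 and LG1 (Os04g0656500), a leaf joint gene, by 1.37, and the gene that fell was GSK2 (camera adjusted p = 0.624). GSK4 rose by 0.62, a call that was lost with libraries scaled to equal totals (0.31, adjusted p = 0.106). Of 8 genes of leaf angle and grain size, a list added after the values were in hand, 2 rose, LG1 and BG1 (Os03g0175800), the latter by 1.97 (camera adjusted p = 0.125).

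All 4 phenylpropanoid and lignin genes fell. PAL4 fell by 3.22 ± 0.40 (SE, limma adjusted p = 0.00331), CAD2 was 4.92-fold and 4CL3 4.32-fold lower, and COMT1 was 2.88-fold lower with a call lost without GSK2-RNAi replicate 2 (adjusted p = 0.0512). Of the 4 chlorophyll breakdown genes 2 fell. RCCR1 fell by 3.48, and SGR was 8.57-fold lower, a call lost without GSK2-RNAi replicate 1, 2 or 3 (adjusted p = 0.0502, 0.0896 and 0.054) and without GSK2-RNAi oswrky53 replicate 2 (0.057). In the list of defence proteins and signalling 1 of 15 rose, RAC1, and 4 fell. CHT3 fell by 4.98, NPR1 was 3.84-fold lower and SGT1 (Os01g0624500), a cochaperone gene, 1.57-fold lower (camera adjusted p = 0.136). CHT1 was 5.36-fold lower, a call lost without GSK2-RNAi replicate 2 or 3 (adjusted p = 0.0641 and 0.0663) and without GSK2-RNAi oswrky53 replicate 1 or 2 (0.0509 and 0.0556). RAC1 was 6.38-fold higher, a call lost without GSK2-RNAi replicate 2 or 3 (0.0684 and 0.0662) and without GSK2-RNAi oswrky53 replicate 2 or 3 (0.0625 and 0.0713). Of 11 diterpenoid phytoalexin genes 3 rose and 2 fell. CPS4 was 22.4-fold lower (camera adjusted p = 0.994 for the list). CPS2 (Os02g0571100) was 4.62-fold higher, a call lost without GSK2-RNAi replicate 2 or 3 (adjusted p = 0.0999 and 0.1) and without GSK2-RNAi oswrky53 replicate 2 or 3 (0.11 and 0.103) and with eBayes without trend (0.0751), and KSL5 was 5.36-fold higher, a call lost without GSK2-RNAi replicate 1, 2 or 3 (0.0502, 0.0866 and 0.0637). In the WRKY list 0 of 6 rose and 2 fell (camera adjusted p = 0.0979). WRKY76 was at 3.3, 4.4 and 1.0 normalized counts in the libraries labelled GSK2-RNAi oswrky53 and at 281, 705 and 1551 in those labelled GSK2-RNAi (limma adjusted p = 0.00511), and the wild type libraries held 2124 and 90.2. WRKY62 was at 0, 3.3 and 0 against 68.1, 157 and 293 (adjusted p = 0.00402), with 78.1 and 12.3 in the wild type. In the jasmonate list 1 of 12 fell (camera adjusted p = 0.136). Among markers of other tissues and states, 0 of 5 genes of dividing cells passed, 1 of 4 pollen and anther genes rose, and of 12 genes of water stress and abscisic acid 1 rose and 1 fell. Of 6 floral organ and panicle genes 1 fell, MADS3 (Os01g0201700), which was 10.35-fold lower, and of 11 heat shock genes 1 rose, HSFA2D, by 1.27.

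With libraries scaled to equal totals the median of all genes fell by 0.32 on the log2 scale and 1144 of 7338 changed genes were higher, against 2223 of 4172 with the deposited scaling. The count fell to 2374, 1575 and 2136 without GSK2-RNAi replicate 1, 2 and 3 and to 2302 without GSK2-RNAi oswrky53 replicate 3. Of 60 called genes chosen for naming, 28 lost the call without at least 1 of the libraries.

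**Figure D2:**
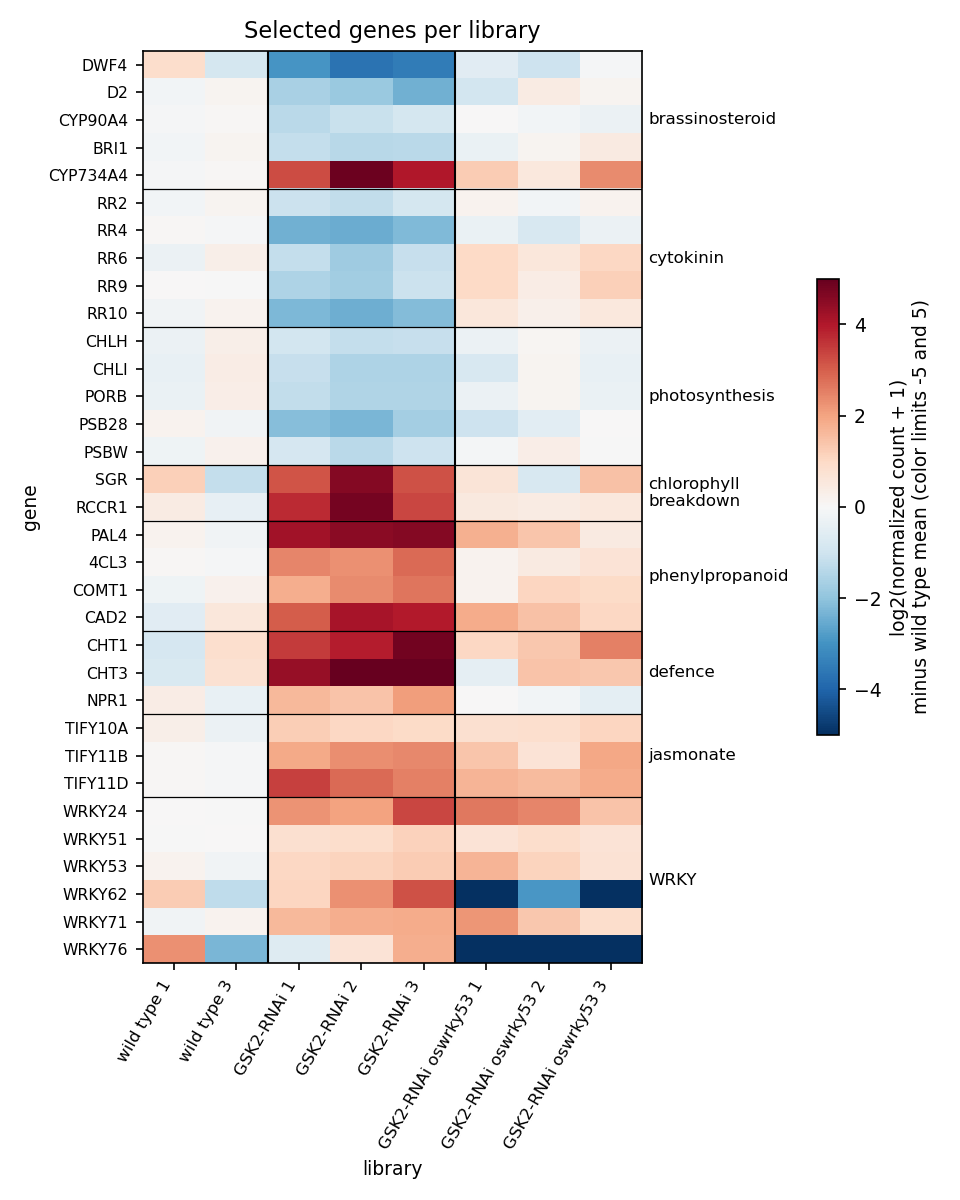
Selected genes of the lists in each library, as log2(normalized count + 1) minus the wild type mean; red is higher and blue lower than the wild type, with colors limited at -5 and 5. RR4, RR10 and DWF4 are blue and RCCR1, PAL4 and CHT3 red in the 3 libraries labelled GSK2-RNAi, and WRKY76 is blue in the 3 libraries labelled GSK2-RNAi oswrky53.

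The return of changed genes toward the wild type was measured among the 6290 genes that differed between the libraries labelled GSK2-RNAi and the wild type. In the libraries labelled GSK2-RNAi oswrky53, 98.2% of them moved opposite to their first change, and 3312 did so past the threshold. Among named genes with a mean of at least 50 over the libraries, those whose smaller change was largest were CHT3, CPS4, SGR, RCCR1, DWF4, CYP734A4, RAC1 and CHT1. Of the genes that rose first, 1636 of 3364 then fell, where independent lists would share 259. Of those that fell first, 1676 of 2926 then rose, where independent lists would share 257. The median gene lost 66.3% of its first change. Both comparisons use the libraries labelled GSK2-RNAi with opposite sign, so 100 data sets were simulated in which the libraries labelled GSK2-RNAi oswrky53 did not differ from those labelled GSK2-RNAi. With noise drawn separately for each gene, they gave a share of 54.5% on average, with a highest of 56.4%. The covariance of the log2 fold changes of the comparisons across genes was -0.80, against -0.08 in the simulated data. The 3 shared libraries cannot be split into parts of at least 2, so part of the excess over independent lists may come from sharing them.

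**Figure D3:**
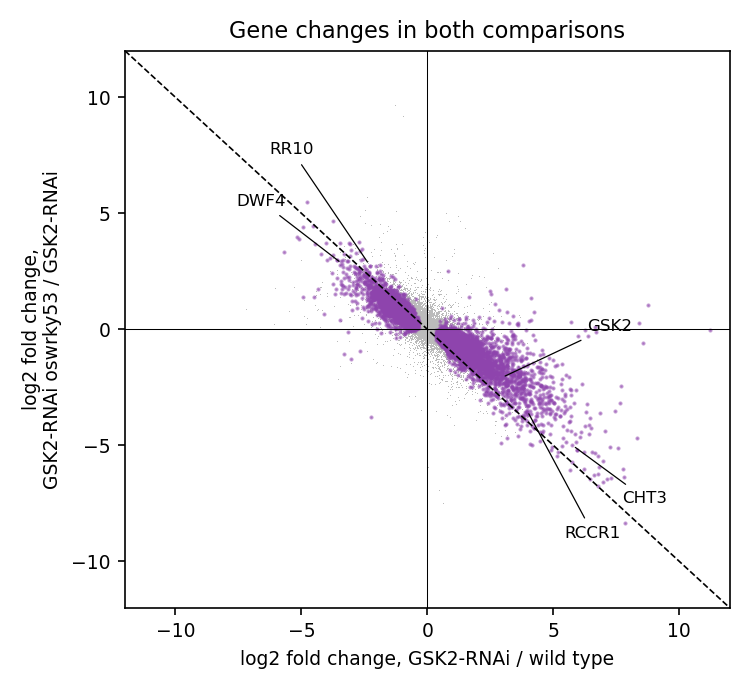
Each point is a gene, with the log2 fold change of the libraries labelled GSK2-RNAi over the wild type on the x axis and of the libraries labelled GSK2-RNAi oswrky53 over those labelled GSK2-RNAi on the y axis; purple points are the 6290 genes changed in the first comparison, and the dashed line marks a full return. Of the purple points 98.2% have opposite signs on the axes, and the libraries labelled GSK2-RNAi enter both axes.

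The comparison of the libraries labelled GSK2-RNAi oswrky53 with the wild type asked how far plants with both changes differ from the wild type. Of 231 named genes, WRKY53 among them, 0 passed the threshold (limma). Adjusted over the list alone, the members that were higher and lower numbered 5 and 1 for brassinosteroid signalling, 4 and 2 for WRKY genes, 4 and 1 for cytokinin and 4 and 0 for jasmonate. The jasmonate list, with 0 of 12 members past the threshold over all genes, had an upward set call (camera adjusted p = 0.00141) that was lost with an estimated correlation (adjusted p = 0.368 with an estimated correlation) and without wild type replicate 3 (adjusted p = 0.0568). TIFY11D was at 34.7 ± 3.13 against 9.85 ± 0.449 normalized counts in the wild type (adjusted p = 0.0931 over all genes), and WRKY76 had an adjusted p of 0.0718. Over all genes 85 of 25325 changed, 78 upward and 7 downward, and 3283 had an unadjusted p under 0.05. Of the 6290 genes changed in the libraries labelled GSK2-RNAi against the wild type, 90.6% had the same sign here. Their median was 33.7% of that first change. This restates the median loss of 66.3% given above, since in 1 fit this difference is the sum of the others. Sharing the wild type libraries favours the same sign. The 85 changed genes have no checked name, and examples were chosen after their values were seen. Os03g0115800 was listed at 0 in both wild type libraries and at 2875, 1708 and 2636 in those labelled GSK2-RNAi oswrky53 (limma adjusted p = 2.54e-07), and Os08g0410900 at 1.4 and 0 against 1260, 1636 and 1323 (adjusted p = 9.94e-06). Both were also high in the libraries labelled GSK2-RNAi, at 2199.6, 2368.7 and 2577.5 and at 761.3, 586.0 and 681.8. Os08g0332100 was at 355 and 230 (wild type) against 4.4, 2.2 and 4.2 (adjusted p = 0.000269), and Os06g0197575 at 224 and 35.1 against 0 in all 3 libraries (adjusted p = 0.0113). In the libraries labelled GSK2-RNAi these were at 58.4, 51.2 and 73.0 and at 177.7, 66.5 and 161.2. All 25 lists had 0 members past the threshold over all genes here. Of the 85 genes, 57 had also changed the same way in the libraries labelled GSK2-RNAi against the wild type, 52 upward and 5 downward, where independent lists would share 10.4 and 0.81. Both comparisons use the same wild type libraries, which cannot be split into parts of at least 2, so part of this sharing may come from them. In 100 data sets with the libraries labelled GSK2-RNAi oswrky53 simulated as unchanged from the wild type, 0.09 genes changed and 0.08 were shared on average, too few to judge the sharing by. The count fell to 54 without wild type replicate 1, to 53 without wild type replicate 3 and to 53 without GSK2-RNAi oswrky53 replicate 2.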

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

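Scaling to equal library totals and lists of only the members written first were chosen after the data were seen, and the other alternatives before. The scaling gave 9507 changed genes for the libraries labelled GSK2-RNAi against the wild type, 7338 for those labelled GSK2-RNAi oswrky53 against those labelled GSK2-RNAi, and a returning share of 98.7%; it shifts all genes up in the first comparison and down in the second, so it favours opposite signs by its construction. Requiring a 2-fold change gave 3807 and 2195, because fewer genes qualify. For the libraries labelled GSK2-RNAi oswrky53 against the wild type, where 85 genes changed, the count was 56 with the stricter filter, 44 with only the compared groups in the fit and 134 for genes with a changed transcript; the cause was not tested. With an estimated correlation 0 of the 9 list calls remained. With fry, a planned set test of the members without regard to other genes, all 9 remained and 13 were made. The further calls, all upward, included brassinosteroid synthesis and breakdown (fry adjusted p = 0.0217) and leaf angle and grain size (fry adjusted p = 0.0165). Both were for the libraries labelled GSK2-RNAi oswrky53 against those labelled GSK2-RNAi. The others were ethylene calls. The sign of the WRKY53 difference between the libraries labelled GSK2-RNAi oswrky53 and GSK2-RNAi, 0.03 and not called, turned to -0.32 with quantile normalization, -0.28 with equal totals, -0.02 without GSK2-RNAi replicate 1 and -0.23 without GSK2-RNAi oswrky53 replicate 1, within a leave-out range of -0.23 to 0.25. Apart from these, the replicate block and the left-out libraries, the planned settings kept the counts within 1.5 times.

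Leaving out each library in turn, where a lone wild type library is assumed to vary like the other groups, gave 3670 to 4705, 1575 to 3680 and 53 to 64 changed genes in the 3 comparisons, a GSK2 log2 fold change of 2.90 to 2.98, a WRKY53 log2 fold change of 0.988 to 1.303 over the wild type, a returning share of 97.3% to 98.5% and 7 to 13 list calls. Same-numbered libraries did not deviate together (correlations of deviations from -0.21 to 0.15), so the numbers were not taken to pair the libraries; with the replicate block, a planned setting, the counts were 3894, 2621 and 32, over 1.5 times lower, and of the named genes' values 91 kept their side of the threshold and 37 calls were lost, among them those of Hd3a, SGR, KSL5, KSL6, CPS2, RAC1, GID1, SD1, PT8 and SWEET14. Over the named genes and every setting, 2026 values kept their direction and side of the threshold, 305 kept the direction and lost the call, and 4, those of WRKY53, changed sign. The 2-fold changes recovered in the simulated libraries ranged from 23.0% to 43.0%; what depth limits was not tested. Count tests were not run, because whole reads were not recovered.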

Other observations

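Set tests of gene lists were planned, and most lists were planned by name. That of leaf angle and grain size was added after the data were seen. Several planned lists were joined after the name check, photosynthesis and chlorophyll synthesis and clock and flowering time among them. Most members were written after the table of values had arrived, though before any comparison. The tests of explanations for the GSK2 level, the return toward the wild type and the 85 genes were chosen after these results were seen, and the scaling to equal library totals after the totals were seen. Hormone genes outside the groups above changed in both directions. Of 9 gibberellin genes 1 rose and 2 fell in the libraries labelled GSK2-RNAi against the wild type (camera adjusted p = 0.901): the synthesis gene KS1 (Os04g0611800) was 2.14-fold lower and the receptor gene GID1 (Os05g0407500) 1.65-fold higher (log2 fold changes of -0.72 and 1.11 with libraries scaled to equal totals). In the libraries labelled GSK2-RNAi oswrky53 against those labelled GSK2-RNAi, 3 of these 9 rose, KS1 among them by 0.97, and 1 fell (camera adjusted p = 0.55). The fall was that of GID1 (adjusted p = 0.0493), a call lost with pseudocount 0.5 (0.0501), no filter (0.0591), trimmed mean of M values (0.0588), eBayes without trend (0.0929) and robust eBayes (0.0594) and without any 1 of the 6 libraries compared (0.0514 to 0.145). A further rise, that of SD1 (Os01g0883800, adjusted p = 0.0408), was lost with quantile normalization (0.0717), equal totals (0.0903), eBayes without trend (0.0748) and only the compared groups in the fit (0.0505), and without GSK2-RNAi replicate 2 (0.0608) or GSK2-RNAi oswrky53 replicate 1, 2 or 3 (0.08, 0.0844 and 0.103); without GSK2-RNAi replicate 3 it was 0.67 in place of 1.06. Of 10 auxin response genes 1 rose, IAA1 (Os01g0178500), by 0.82, and 1 fell in the first comparison (camera adjusted p = 0.446), and 1 rose in the second (camera adjusted p = 0.994). Of 7 ethylene genes 1 rose and 1 fell in the first comparison (camera adjusted p = 0.834), and 1, the receptor gene ERS2 (Os05g0155200), rose in the second, by 0.86, and by 0.55 with libraries scaled to equal totals (camera adjusted p = 0.624).

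In the first comparison 2 of 15 sucrose and starch genes rose and 1 fell (camera adjusted p = 0.995). The sugar transporter gene SWEET14 (Os11g0508600) was 2.74-fold higher, with a call lost without wild type replicate 3 or GSK2-RNAi replicate 3 (adjusted p = 0.0896, with a log2 fold change of 0.99, and 0.0534). In the second comparison 3 rose and 1 fell, and SWEET4 (Os02g0301100) was 2.37-fold higher (camera adjusted p = 0.803). Of 7 phosphate starvation genes 1, the phosphate transporter gene PT8 (Os10g0444700), rose in the first comparison, 4.41-fold higher at 4120 against 933 normalized counts (camera adjusted p = 0.834), and had an adjusted p of 0.0491 in the second, where 0 of the 7 passed adjusted over the list alone (camera adjusted p = 0.624). That call was lost with pseudocount 0.5 (0.0502), no filter (0.0548), trimmed mean of M values (0.0518), eBayes without trend (0.0872), robust eBayes (0.0512), library weights (0.0549) and only the compared groups in the fit (0.0604), and without GSK2-RNAi replicate 1 or 3 (0.103, and 0.082 with a log2 difference of -0.48) or GSK2-RNAi oswrky53 replicate 1, 2 or 3 (0.0936, 0.0997 and 0.118). Of 6 cellulose synthase genes and 7 expansin and xyloglucan enzyme genes 0 passed the limma threshold in any of the 3 comparisons (camera adjusted p = 0.995 for each in the first). Of 8 genes of leaf angle and grain size 0 passed in the first comparison (camera adjusted p = 0.446), and of 8 genes of nitrogen uptake and assimilation 2 rose in the second (camera adjusted p = 0.207).

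GSK2 reads were highest in the libraries labelled for its silencing. A single wrong label or a swap of 2 libraries is argued against, since 0 libraries of the other groups reached the lowest of these 3. More GSK2 activity there, and likewise a whole exchange of the labels of wild type and GSK2-RNAi, would by the feedback known for brassinosteroids raise synthesis genes in the libraries labelled GSK2-RNAi, where 4 fell and 0 rose; this goes against both, but the feedback was not measured in these leaves, so both stay open. For the exchange the other values point both ways: of the genes at the floor in 1 of these groups alone, 100% (8 of 8 in only 7 places, exact 95% interval 63.1% to 100%) were at the floor in the wild type, as the labels would have it, whereas the libraries labelled wild type and GSK2-RNAi oswrky53 differed in 85 genes against 6290 and had Spearman correlations of 0.956 to 0.974, as an exchange would have it. An exchange would also have it that genes are present only where labelled GSK2-RNAi. There were 4 of these, at the floor in the groups labelled wild type and GSK2-RNAi oswrky53 and at 50 or more where labelled GSK2-RNAi. Genes at the floor in both groups labelled with the construct and at 50 or more in the wild type numbered 0. A candidate explanation is that reads of the construct were counted as GSK2, which would place both construct-bearing groups above the wild type; the libraries labelled GSK2-RNAi oswrky53 lay 0.85 above it on the log2 scale, and read positions within the gene, which would decide, were not analysed here.

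The return toward the wild type exceeds what noise drawn separately for each gene in the shared libraries gives. Of the genes, 98.2% moved back, against at most 56.4% in simulated data. A deviation common to many genes of the libraries labelled GSK2-RNAi was not simulated, so the simulated data cannot decide on it. Scaling to equal library totals shifts all genes up in the first comparison and down in the second, so the 98.7% it gave decides nothing for genes that rose and then fell. Of the 1463 genes that still fell under it, 98.2% (95% interval 97.4% to 98.8%) moved up afterwards, against the shift. The interval treats genes as independent and leaves out the spread between libraries. The share argues against library totals for these genes. The planned scalings moved the median of all genes little. For both directions together they gave a share of 98.3% (quantile) and 98.2% (trimmed mean of M values), so the share did not hinge on the choice between them. The 6 libraries of the second comparison allow 10 splits, too few for a share under 0.05; the real split gave 4172 genes, 1 split of the 10 reached that, and the highest other gave 0. The exchange of labels above stays open, and under it there would be no return. If the labels hold, the WRKY53 mutation and a weaker construct cannot be told apart as sources of the return. GSK2 reads were also lower in the libraries labelled GSK2-RNAi oswrky53, by a log2 difference of -2.09. No library carries the mutation without the construct. A difference in sampling or stage limited to the libraries labelled GSK2-RNAi would also give a return, and it was not tested. Those libraries alone had the lower share of the most abundant genes given above. A hypothesis under the labels is that the return may follow from the mutation, from a weaker construct or from such a difference in sampling. A group with the mutation alone, not analysed here, would show the mutation without the construct, but not the strength of the construct.

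The 85 genes that separated the libraries labelled GSK2-RNAi oswrky53 from the wild type were mostly higher, 57 had changed the same way in the libraries labelled GSK2-RNAi, and 26 were at the floor (at most 3 approximate reads per library) in both wild type libraries, against 1 at the floor in all libraries labelled GSK2-RNAi oswrky53. Stretches of the genome that differ between the plant lines may be a source. Of the 85, 9 pairs lay within 10 places of each other along a chromosome, against a mean of 2.79 in 10000 random draws (permutation p = 0.0029, one-sided). The same number of genes with the smallest p in the libraries labelled GSK2-RNAi against the wild type gave 7 pairs. That comparison sets another labelled line against the same wild type libraries, so its pairs count neither for nor against this source. A general response of the leaf stays open as well. Of the 85, 27 (31.8%) were at the floor in a whole compared group, against 22 of 85 (25.9%) genes with the same size of change in that other comparison. These 22 decide nothing, because the matched genes were drawn from all genes called there. The 57 shared genes were not left out of the draw, so a gene could be matched with itself. A first control, the 85 genes of that comparison with the smallest p, gave 9. The size-matched control replaced the first after its result had been seen, so this reading rests on that choice. These explanations cannot be told apart without the sequences of the lines, which were not analysed here.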
